A study of Mus musculus with 9 samples.

How the data were processed

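RNA from the livers of 9 female mice was measured on Affymetrix mouse expression arrays, with 1 array per mouse and no pooling. The description of the treated samples speaks of rats, while their organism, source name and strain give mouse, as does the array, so all samples were treated as mouse. The labels give 3 groups of 3 mice: a control diet, a diet with permethrin and a diet with clofibrate. Per the labels, biotin-labelled cRNA was made from total RNA and the authors computed MAS5 values; the version and settings of MAS5 are not given in the sources used here. The table deposited by the authors holds 1 linear signal per probe set and array, in units of intensity. On every array the mean signal without the lowest and highest 2% of probe sets was 100.001, so each array had been scaled to that trimmed mean. The values are not log-transformed. No 2 arrays shared more than 1 identical probe set signal, and 0 columns belonged to samples outside the series.

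The table has 45101 rows, of which 64 are control probe sets of the array. Of the remaining 45037 probe sets, 34945 were assigned to 1 gene symbol, 932 to several and 9160 were unnamed here. Symbols were updated through Entrez gene identifiers for 34741 probe sets. An offset of 3.35, the 20th percentile of all signals, was added before taking log2. Probe sets were tested when their signal was above 15.6, the median of all signals, in at least 3 arrays. This left 24546 probe sets, of which 21388 carried 1 symbol, 602 several and 2556 none. A gene was represented by its tested probe set with the highest mean log2 signal, which gave 12476 genes, 5398 of them with several tested probe sets. Genes are named only from probe sets assigned to 1 gene. Of the 1006 symbols in the gene lists, 823 had such a probe set. Cyp4a10 and Gapdh had none and were not analysed here. Some genes of the fixed marker set are not reported here. Genome coordinates were not used here.

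Groups were compared with limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8. All 9 arrays entered a single linear model with a mean per group, followed by moderated statistics with an intensity trend. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over the 24546 probe sets within each comparison, with a threshold of 0.05. The comparisons were permethrin against control, clofibrate against control and permethrin against clofibrate. The last is also the test of the difference between the first 2. Unless stated otherwise, ± after a signal is the standard deviation and ± after a log2 fold change is the standard error, with n = 3 arrays per group.

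The 44 gene lists covered lipid metabolism, targets of xenobiotic receptors, plasma proteins, nitrogen and glucose metabolism, stress responses, the cell cycle, sex-biased genes, hepatocyte zones and markers of other cell types. They were tested with camera, part of limma, at a preset inter-gene correlation of 0.01, with adjustment over the 41 lists that had at least 5 tested genes. camera asks whether a list's genes shifted in 1 direction relative to the other genes. A list whose genes change in both directions can therefore stay uncalled. The correlation was also estimated per list. Some genes are in several lists, so calls of different lists are not independent. As a further alternative, fry was run. Its test in 1 direction asks whether a list's genes move, on balance, one way, and its mixed test whether they change in either direction. Neither compares the list with other genes.

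The groups, comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. The rule named, for each treated group against control, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose 3 treated arrays all lay on 1 side of the 3 control arrays. For permethrin against clofibrate it named 6 and 6. It also named a fixed set of marker genes of nuclear receptor activity and cell division, and up to 4 members of each list with the largest changes. Other genes were chosen after their values were seen, and are marked as such.

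Alternatives changed 1 choice at a time. They covered the offset, the normalization, the filter on dim probe sets, the variance model, array weights, the arrays in the model, a threshold of 2-fold, the choice of probe sets per gene, a block for the replicate number, and leaving out each array in turn. Cyclic loess normalization and scaling to the hybridization controls, which are transcripts added in fixed amounts, were chosen after seeing the data. The replicate numbers are not said to pair mice, and deviations of arrays with the same number correlated between -0.109 and 0.113, so no pairing was used. Batch labels are not given in the sources used here.

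The overlap of the first 2 comparisons was set against simulations in which treated groups did not differ from the shared controls, 100 for the correlation and 20 for the calls. The model was tested on simulated data with the spread of these arrays. It recovered between 11.9% and 14.9% of genes changed 1.5-fold, between 49.3% and 55.2% of genes changed 2-fold and between 84.8% and 87.9% of genes changed 4-fold. The share of false calls was at most 1.68%. False calls were 1 of 117 for permethrin against control, 2 of 119 for clofibrate against control and 0 of 117 for permethrin against clofibrate. In each comparison 67 of 12476 simulated genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. The real data gave up to 877 called genes. The simulated recovery and share of false calls therefore need not hold for the results given here. The number of arrays limits the precision of each value. Detection calls were not used, so signals near background were removed only by the filter.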

Results

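The data are liver expression signals from 9 female mice of the outbred stock Crlj:CD1(ICR). The control diet, a diet with 5000 ppm permethrin and a diet with 5000 ppm clofibrate were each fed to 3 mice for 2 weeks. Permethrin is a pyrethroid insecticide. Clofibrate is a lipid-lowering drug of the fibrate class, whose members activate PPAR alpha, a nuclear receptor that controls genes of fatty acid breakdown. The median signal per array lay between 13.4 and 17.9. Across probe sets, which are not independent replicates, the correlation of log2 signals was 0.959 to 0.970 between arrays of the same group and 0.948 to 0.966 between arrays of different groups.

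Some measures of array quality differed between the groups. The highest signal of an array was 14386.9 to 14898.7 in controls, 12791.6 to 13408.5 with permethrin and 10713.6 to 12057.7 with clofibrate. The 18S ribosomal RNA probe set had a signal of 199 ± 8.48 in controls, 92.6 ± 42.0 with permethrin and 103 ± 20.7 with clofibrate (SD, n = 3). The ratio of 3' to 5' Gapdh signal was 0.967 ± 0.0656 in controls, 0.870 ± 0.0341 with permethrin and 0.870 ± 0.0215 with clofibrate (SD, n = 3). The hybridization controls, added to every array in fixed amounts, had a mean log2 signal of 10.38 ± 0.14, 10.25 ± 0.19 and 10.02 ± 0.16 in the same order (SD, n = 3). Scaling each array to these controls moved the log2 change of the median gene by 0.13 for permethrin against control, by 0.34 for clofibrate against control and by -0.22 for permethrin against clofibrate. Medians under that scaling are therefore also given relative to the median gene.

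The comparison of permethrin with control asks which liver genes differ after feeding the insecticide. Cd36, which takes up fatty acids at the cell surface, rose 12.5-fold, from a signal of 139 ± 34 in controls to 1752 ± 189 with permethrin (SD, n = 3). Acot1, a thioesterase that splits fatty acyl-CoA, rose 8.44-fold, from 263 ± 44.8 to 2236 ± 307 (SD, n = 3). The drug-metabolizing cytochrome P450 Cyp2b10, a marker of the nuclear receptor CAR, rose 4.86-fold, from 836 ± 234 to 3985 ± 309 (SD, n = 3). Cela1, a pancreatic-type elastase, fell 6.33-fold, from 1295 ± 189 to 207 ± 69.2 (SD, n = 3). Of 12476 genes, 265 passed the limma threshold, 160 higher and 105 lower with permethrin. The pancreas marker list, which holds Cela1, was lower with permethrin, with Cela1 as the 1 of its 6 tested genes past limma (2 lower adjusted over the list alone, median -0.63, camera adjusted p = 0.00793, adjusted p = 0.122 with an estimated correlation).

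**Figure D1:**
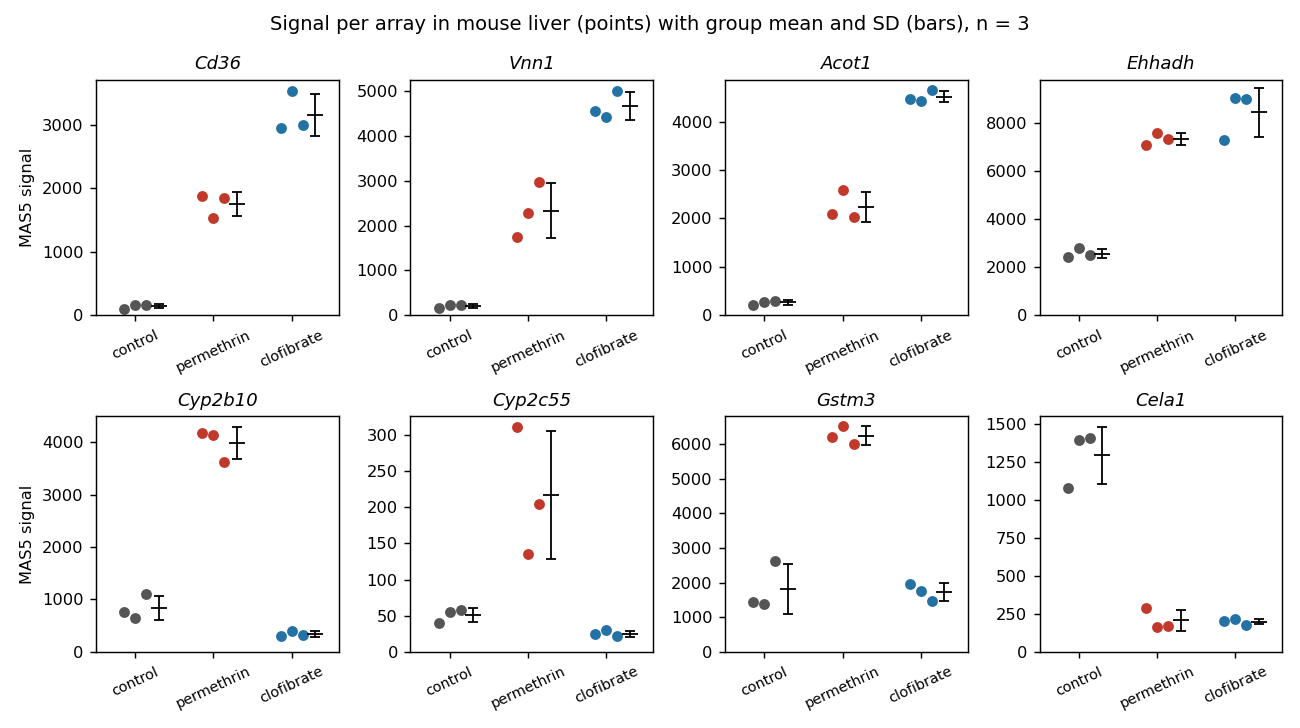
Signal of 8 genes in each liver, in intensity units on linear axes that start at 0; points are single arrays, and bars show the mean and SD of 3 arrays per group. Cd36, Vnn1, Acot1 and Ehhadh were higher in both treated groups, Cyp2b10, Cyp2c55 and Gstm3 were higher with permethrin than with clofibrate, and Cela1 was lower in both treated groups.

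Genes of fatty acid breakdown rose with permethrin. In peroxisomal fatty acid oxidation, 9 of 29 tested genes rose and 1 fell (13 and 2 adjusted over the list alone). The list's median log2 change was 0.44 (camera adjusted p = 1.83e-10, adjusted p = 0.13 with an estimated correlation). Ehhadh, the peroxisomal bifunctional enzyme, rose from 2557 ± 194 to 7325 ± 245 (SD, n = 3), and Crat, carnitine acetyltransferase, rose 3.24-fold. In mitochondrial fatty acid oxidation, 8 of 23 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.41, camera adjusted p = 5.23e-12, adjusted p = 0.123 with an estimated correlation). Its members Acot2, Slc22a5, the carnitine transporter, and Eci1 rose 4.14-fold, 3.11-fold and 1.98-fold. Peroxisome assembly had 4 genes higher of 21 and 0 lower (7 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 0.000171, adjusted p = 0.123 with an estimated correlation). Among them Pex11a, which drives peroxisome division, rose 4.20-fold. In microsomal omega oxidation, 2 of 10 rose and 1 fell (3 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.249). Its member Cyp4a12a rose from 196 ± 131.7 to 2101 ± 349 (SD, n = 3), a log2 change of 3.67, or 3.01 without control replicate 3. Aldh3a2 rose 2.93-fold. Cyp4a14 in the same list had a log2 change of 2.23 ± 0.57 (limma adjusted p = 0.0863), which was 1.31 without control replicate 2 and 2.87 without control replicate 1, past the threshold in both cases.

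Genes that take up, store and make lipid rose as well. Lipid droplet genes rose in 7 of 21 cases and fell in 0 (10 and 1 adjusted over the list alone, median 0.61, camera adjusted p = 6.03e-09, adjusted p = 0.122 with an estimated correlation). Fitm2, needed for lipid droplet formation, rose 3.49-fold. Of 19 fatty acid uptake genes 3 rose, Cd36 and Lpl among them, and 0 fell (4 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 0.000554, adjusted p = 0.451 with an estimated correlation). Fatty acid and triglyceride synthesis had 3 of 28 genes higher and 0 lower (6 and 2 adjusted over the list alone, median 0.25, camera adjusted p = 0.000124, adjusted p = 0.451 with an estimated correlation). Mogat1, which makes diacylglycerol, rose from 15.5 ± 9.81 to 152 ± 59.1 (SD, n = 3), and Me1, malic enzyme, rose 3.14-fold. The control signal of Mogat1 is near the filter, so its fold change depends on the offset. Among other PPAR alpha targets, 3 of 22 rose and 0 fell (8 and 1 adjusted over the list alone, median 0.21, camera adjusted p = 0.000172, adjusted p = 0.166 with an estimated correlation). Vnn1, a pantetheinase, rose 11.3-fold, from 201 ± 43.9 to 2332 ± 613 (SD, n = 3). Of the marker genes fixed for PPAR alpha, Cpt1a had a log2 change of 0.05 ± 0.13 and Angptl4 of 0.20 ± 0.23, neither past the threshold.

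NRF2 and CAR targets were higher with permethrin. Both lists hold Gstm3, so their calls are not independent. Targets of NRF2, the transcription factor of the oxidant response, rose in 12 of 29 cases and fell in 0 (19 and 0 adjusted over the list alone). Their median log2 change was 0.59, and the camera call held with an estimated correlation (adjusted p = 1.26e-22, and 0.00106 with the estimate). Gstm3 and Gsta2, glutathione transferases, rose 3.61-fold and 2.47-fold, and the efflux pump Abcc4 rose 7.86-fold. Nqo1, a widely used NRF2 marker, had a log2 change of 0.59 ± 0.14 (limma adjusted p = 0.0757). Of 30 CAR targets, 8 rose and 0 fell (9 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.000129, adjusted p = 0.122 with an estimated correlation). The lists of PXR targets, AHR targets and phase II conjugation were not called (camera adjusted p = 0.918, 0.885 and 0.205), though phase II conjugation was in 1 of 20 settings. Besides Cyp2b10, Cyp2c55 rose 3.87-fold, and Cbr3, a carbonyl reductase, rose from 13.6 ± 5.30, below the filter, to 129 ± 14.2 (SD, n = 3). Gstm3, Gsta2 and Cbr3 belong to families with related sequences, and a probe set may also read a relative.

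Genes of protein turnover rose in part. The heat shock list had 2 of 14 genes higher and 0 lower (7 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 1.08e-06, adjusted p = 0.122 with an estimated correlation). The proteasome list had 3 of 31 higher and 0 lower (11 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 1.71e-10, adjusted p = 0.122 with an estimated correlation). Cholesterol synthesis had a median of 0.37 and a camera adjusted p of 0.000607 (adjusted p = 0.451 with an estimated correlation). In that list 0 of 21 genes passed limma, 0 adjusted over the list alone, and 7 had an unadjusted p under 0.05.

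Genes for plasma proteins and amino acid breakdown were lower with permethrin. The complement and coagulation list fell in camera, with 5 of 34 genes lower and 0 higher (24 and 0 adjusted over the list alone). Its median log2 change was -0.37, and the call held with an estimated correlation (adjusted p = 8.87e-17, and 0.0379 with the estimate). Under scaling to the hybridization controls the median was -0.24, or -0.32 relative to the median gene, and 2 genes were lower. C1s1, a complement protease, fell from 1967 ± 144 to 1026 ± 171 (SD, n = 3). The urea cycle and amino acid list had 6 of 42 genes lower and 1 higher (22 and 1 adjusted over the list alone, median -0.34, camera adjusted p = 1.95e-10, adjusted p = 0.179 with an estimated correlation). The gene that rose was Csad, which makes the taurine precursor hypotaurine, by 4.04-fold. The acute phase list had a median of -0.28 and a camera adjusted p of 1.08e-06 (adjusted p = 0.122 with an estimated correlation). It had 0 of 32 genes past limma, 13 with an unadjusted p under 0.05 and 7 lower adjusted over the list alone. The counts of the urea cycle and acute phase lists are given without scaling to the hybridization controls. A bias that depends on signal was not tested for these lists.

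Markers of both hepatocyte zones were lower with permethrin. Their counts are given without scaling to the hybridization controls, under which 23 of all genes were called lower in place of 105. The camera calls of both zone lists at the preset correlation were lost in 0 of 20 settings. A bias that depends on signal was not tested for them. The periportal list had 3 of 17 genes lower and 0 higher (9 and 0 adjusted over the list alone, median -0.44, camera adjusted p = 3.85e-08, adjusted p = 0.122 with an estimated correlation). Its member Apoa4, an apolipoprotein, fell from 2566 ± 288 to 1093 ± 159 (SD, n = 3). The pericentral list had 4 of 20 lower and 0 higher (6 and 0 adjusted over the list alone, median -0.26, camera adjusted p = 0.000124, adjusted p = 0.123 with an estimated correlation). Glucose metabolism had 3 of 23 lower and 1 higher (4 and 2 adjusted over the list alone, median -0.22, camera adjusted p = 0.0257, adjusted p = 0.383 with an estimated correlation). Pklr, liver pyruvate kinase, fell from 506 ± 60.0 to 208 ± 14.9 (SD, n = 3). The glucose call ended without control replicate 3, without permethrin replicate 1 and with a filter on the mean signal. Lipoprotein genes had 1 higher, Pltp, and 1 lower, Apoa4, of 27 (1 and 7 adjusted over the list alone, median -0.20, camera adjusted p = 0.0121, adjusted p = 0.467 with an estimated correlation), and that call ended without the same arrays, with each array centred on its median and under scaling to the hybridization controls.

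camera called 20 of the 41 lists, and the NRF2 and complement lists were those that held with an estimated correlation. Among the genes with the largest falls, Inhba, a subunit of activin, fell from 106 ± 10.6 to 17.8 ± 9.11 and the homeobox gene Hlx from 36.8 ± 10.7 to 6.99 ± 1.76 (SD, n = 3). The permethrin signals of Hlx lie below the filter and those of Inhba near it, so the size of both falls depends on the offset. Ptgds, which makes prostaglandin D2, went from 1076 ± 805 in controls to 42.6 ± 12.1 (SD, n = 3; limma adjusted p = 0.008). The groups of all 265 called genes did not overlap, and 22.7% of the 12476 genes had groups that did not overlap, where chance gives 10%. A change of at least 2-fold was seen for 102 called genes, 69 higher and 33 lower. The higher to lower split was 177 to 66 with each array centred on its median and 134 to 23 under scaling to the hybridization controls. Without control replicates 1, 2 and 3 the counts were 108, 174 and 129, and without permethrin replicates 2 and 3 they were 168 and 121.

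The comparison of clofibrate with control shows the response to a fibrate in the same experiment. Vnn1 rose 23.2-fold, from 201 ± 43.9 to 4669 ± 305, and Cd36 rose 22.5-fold, from 139 ± 34 to 3156 ± 330 (SD, n = 3). Acot1 rose 17.1-fold to 4517 ± 114 (SD, n = 3). Cyp2b10 fell 2.39-fold, from 836 ± 234 to 342 ± 53.4 (SD, n = 3), and C1s1 fell 3.15-fold to 621 ± 35.3 (SD, n = 3). Of 12476 genes, 877 passed the limma threshold, 403 higher and 474 lower with clofibrate.

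Fatty acid breakdown genes rose with clofibrate. Peroxisomal fatty acid oxidation had 15 of 29 genes higher and 2 lower (17 and 3 adjusted over the list alone, median 0.65, camera adjusted p = 3.02e-11, adjusted p = 0.131 with an estimated correlation). Crat rose 6.36-fold, Acot3 4.69-fold and Ehhadh 3.29-fold. Mitochondrial fatty acid oxidation had 15 of 23 higher and 0 lower (16 and 0 adjusted over the list alone, median 0.71, camera adjusted p = 4.76e-18, adjusted p = 0.131 with an estimated correlation). Acot2 rose 11.9-fold, Slc22a5 4.84-fold and Eci1 3.44-fold. Peroxisome assembly had 8 of 21 higher and 0 lower (10 and 2 adjusted over the list alone, median 0.19, camera adjusted p = 5.55e-05, adjusted p = 0.131 with an estimated correlation), with Pex11a 5.59-fold and Pex19 1.76-fold higher. In omega oxidation 3 of 10 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.188). Cyp4a12a rose to 3130 ± 1441 (SD, n = 3), a log2 change of 4.13, or 3.47 without control replicate 3. Aldh3a2 rose 4.50-fold, while Cyp4f14 fell 4.54-fold.

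Lipid uptake, storage and synthesis genes rose. Fatty acid uptake had 9 of 19 genes higher and 2 lower (11 and 3 adjusted over the list alone, median 0.63, camera adjusted p = 1.67e-06, adjusted p = 0.194 with an estimated correlation). The fatty acid transporter Slc27a1 rose from 45.3 ± 6.74 to 285 ± 125 (SD, n = 3), and Lpl, lipoprotein lipase, rose 7.76-fold. Lipid droplet genes rose in 11 of 21 cases and fell in 0 (11 and 1 adjusted over the list alone, median 0.71, camera adjusted p = 3.53e-08, adjusted p = 0.131 with an estimated correlation). Fitm1 rose 5.40-fold and Fitm2 2.85-fold. Other PPAR alpha targets had 9 of 22 higher and 0 lower (11 and 2 adjusted over the list alone, median 0.53, camera adjusted p = 1.67e-06, adjusted p = 0.131 with an estimated correlation). Pdk4, which restrains glucose oxidation, rose 4.85-fold and Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, rose 1.64-fold. Fatty acid and triglyceride synthesis had 11 of 28 higher and 1 lower (11 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 0.000155, adjusted p = 0.353 with an estimated correlation). Mogat1 rose from 15.5 ± 9.81 to 537 ± 176 (SD, n = 3).

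Cholesterol synthesis genes rose with clofibrate, 11 of 21 with 0 lower (15 and 0 adjusted over the list alone, median 0.81, camera adjusted p = 7.38e-12, adjusted p = 0.131 with an estimated correlation). Sqle rose from 257 ± 88.5 to 853 ± 313, Cyp51 from 474 ± 37.8 to 1478 ± 312 and Fdps from 1012 ± 220 to 2884 ± 1037 (SD, n = 3). The proteasome list had 10 of 31 genes higher and 0 lower (14 and 0 adjusted over the list alone, median 0.33, camera adjusted p = 3.25e-11, adjusted p = 0.131 with an estimated correlation). The heat shock list had 2 of 14 higher, Hspa1b by 3.66-fold and Hspb1 by 3.06-fold, and 0 lower (5 and 0 adjusted over the list alone, median 0.43, camera adjusted p = 2.68e-05, adjusted p = 0.131 with an estimated correlation). NRF2 targets had 7 of 29 higher and 2 lower (9 and 7 adjusted over the list alone, median 0.18, camera adjusted p = 0.0124, adjusted p = 0.131 with an estimated correlation). Abcc4 rose 4.71-fold and Me1 3.52-fold.

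Complement and coagulation genes fell with clofibrate, 25 of 34 with 0 higher (29 and 0 adjusted over the list alone, median -0.49). Of the 25 lists called by camera among 41, this was the one that held with an estimated correlation (adjusted p = 1.03e-19, and 0.0478 with the estimate). Under scaling to the hybridization controls the median was -0.13, or -0.42 relative to the median gene, and 3 genes were lower. F11, a coagulation factor, fell 2.28-fold. The periportal list had 12 of 17 lower and 0 higher (14 and 0 adjusted over the list alone, median -0.62, camera adjusted p = 2.1e-11, adjusted p = 0.106 with an estimated correlation), with Cdh1 3.55-fold and Apoa4 3.33-fold lower. The urea cycle and amino acid list had 21 of 42 lower and 1 higher (26 and 2 adjusted over the list alone, median -0.42, camera adjusted p = 2.26e-11, adjusted p = 0.153 with an estimated correlation). Prodh, proline dehydrogenase, fell 2.85-fold and Asl, a urea cycle enzyme, 2.09-fold, while Csad rose 4.95-fold. Glucose metabolism had 8 of 23 lower and 2 higher (9 and 3 adjusted over the list alone, median -0.37, camera adjusted p = 0.00601, adjusted p = 0.194 with an estimated correlation). Pklr fell 3.62-fold, and Slc37a4 and G6pc, which together release glucose from glucose 6-phosphate, fell 2.42-fold and 2.40-fold. Of all genes, 474 were called lower with clofibrate, but 77 under scaling to the hybridization controls. The counts of lower genes in the periportal, urea cycle, glucose and phase II lists are given without that scaling. Their camera calls at the preset correlation were lost in 0 of 20 settings.

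Acute phase genes were lower in 10 of 32 cases and higher in 0 with clofibrate (13 and 0 adjusted over the list alone, median -0.35, camera adjusted p = 0.000155, adjusted p = 0.156 with an estimated correlation), but the median was 0.01 under scaling to the hybridization controls, -0.29 relative to the median gene. The acute phase call ended under quantile normalization. The list's members Ahsg and Hamp had control signals from 9870 to 10999, and the highest signal of an array was lower with clofibrate. A bias that depends on signal was not tested for this list. Lipoprotein genes had 11 of 27 lower and 1 higher (15 and 6 adjusted over the list alone, median -0.32, camera adjusted p = 0.00931, adjusted p = 0.353 with an estimated correlation), with a median of 0.04 under scaling to the hybridization controls, -0.25 relative to the median gene. The lipoprotein call ended under that scaling and under quantile normalization. Pltp, the phospholipid transfer protein, was the one that rose, 11.4-fold. The pericentral list had 6 of 20 lower and 0 higher (8 and 0 adjusted over the list alone, median -0.35, camera adjusted p = 0.000233, adjusted p = 0.131 with an estimated correlation), with a median of 0.00292 under that scaling, -0.29 relative to the median gene. Gulo, which makes vitamin C, fell 2.34-fold.

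The CAR, phase II, ER stress and bile acid lists were called lower with clofibrate. CAR targets had 8 of 30 lower and 2 higher (11 and 5 adjusted over the list alone, median -0.28, camera adjusted p = 0.0283, adjusted p = 0.224 with an estimated correlation), but 4 lower and 8 higher with a median of 0.08 under scaling to the hybridization controls, -0.22 relative to the median gene. The CAR call ended under that scaling, under quantile and cyclic loess normalization and without control replicate 3. Cyp2c54 fell from 4646 ± 342 to 1513 ± 414 (SD, n = 3). Phase II conjugation had 6 of 25 lower and 0 higher (11 and 0 adjusted over the list alone, median -0.38, camera adjusted p = 1.44e-05, adjusted p = 0.131 with an estimated correlation). Genes of the endoplasmic reticulum (ER) stress response had 9 of 28 lower and 0 higher (11 and 0 adjusted over the list alone, median -0.40, camera adjusted p = 9.05e-06, adjusted p = 0.131 with an estimated correlation). The chaperone Dnajb11 fell from 427 ± 47.7 to 247 ± 24.5 (SD, n = 3), but under scaling to the hybridization controls its log2 change was -0.42, no longer past the threshold. The ER list then had 0 genes past limma and a median of -0.06, which is -0.36 relative to the median gene, and its camera call at the preset correlation was lost in 0 of 20 settings. Bile acid genes had 6 of 27 lower and 3 higher (11 and 4 adjusted over the list alone, median -0.28, camera adjusted p = 0.0283, adjusted p = 0.194 with an estimated correlation), with a median of 0.09 under scaling to the hybridization controls, -0.21 relative to the median gene. That call ended under this scaling, under quantile and cyclic loess normalization, with the filter at the 75th percentile or on the mean signal, and without control replicate 3 or clofibrate replicate 1. The uptake carrier Slco1a4 fell 4.91-fold. Slc22a7, a carrier that is not in the bile acid list, fell 5.65-fold.

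Stellate and endothelial markers were called lower with clofibrate, both close to the threshold. The stellate cell and fibroblast list had a median of -0.40 (camera adjusted p = 0.0491, adjusted p = 0.472 with an estimated correlation), with 0 of 18 genes past limma, 0 adjusted over the list alone and 5 with an unadjusted p under 0.05. The endothelial list had a median of -0.15 (camera adjusted p = 0.0494, adjusted p = 0.194 with an estimated correlation), with 1 of 18 genes lower, 4 adjusted over the list alone, but its median was 0.20 under scaling to the hybridization controls, -0.10 relative to the median gene. Both calls ended without control replicate 3, permethrin replicate 2 or 3, or clofibrate replicate 1 or 3. The stellate call also ended without control replicate 2, with no filter, with the filter at the 75th percentile and with that on the mean signal, 9 of 20 settings in all. The endothelial call also ended without control replicate 1 or permethrin replicate 1, with the higher offset, with median centring, under scaling to the hybridization controls, with the filter on the mean signal and with the replicate block, 12 of 20 in all.

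The groups of all 877 called genes did not overlap, and 27.2% of the 12476 genes had groups that did not overlap, where chance gives 10%. A change of at least 2-fold was seen for 292 called genes, 177 higher and 115 lower. The higher to lower split was 1153 to 77 under scaling to the hybridization controls. Without control replicates 1, 2 and 3 the counts were 473, 558 and 496, and without clofibrate replicate 3 the count was 430.

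**Figure D2:**
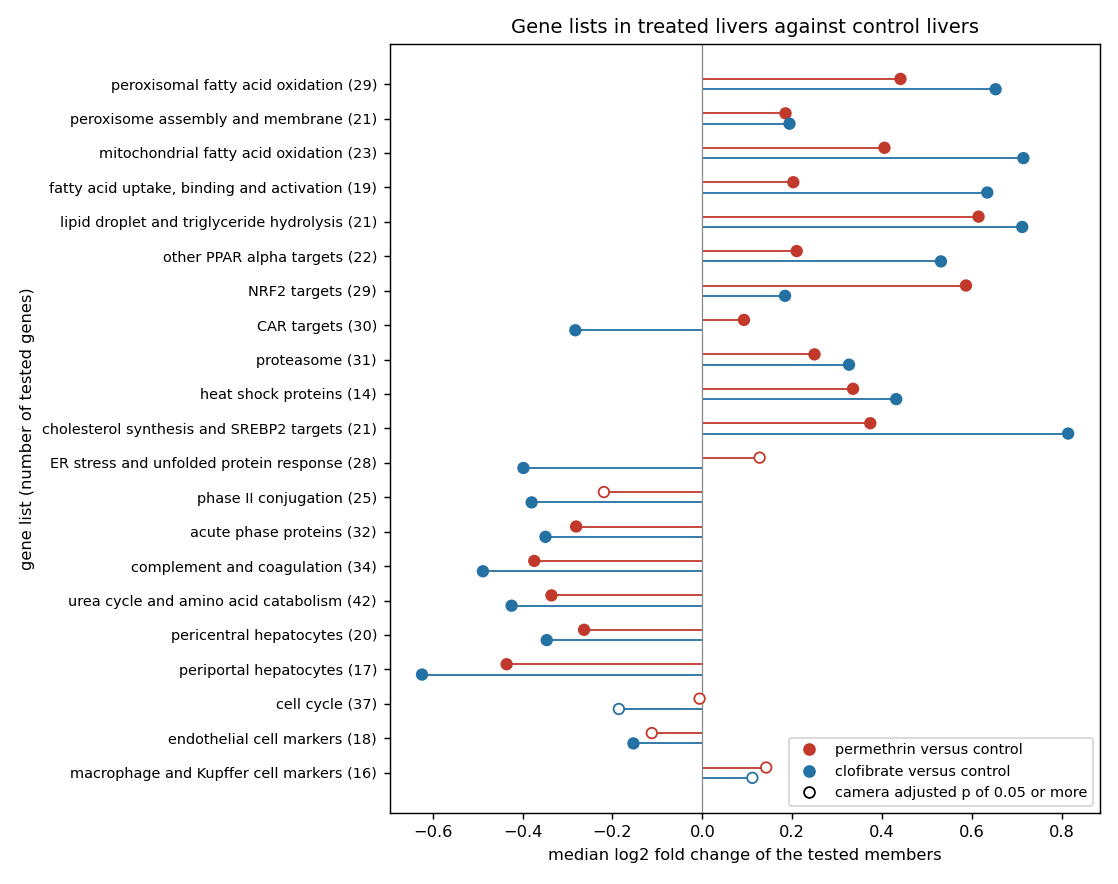
Median log2 fold change of 21 gene lists in each treated group against control; filled points mark lists with a camera adjusted p under the threshold at the preset correlation and open points the others. Mitochondrial fatty acid oxidation had medians of 0.41 with permethrin and 0.71 with clofibrate, and CAR targets had medians of 0.09 and -0.28, the latter 0.08 under scaling to the hybridization controls and -0.22 relative to the median gene there.

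The 2 responses were compared across genes. Of the genes called in both comparisons, 130 were higher in both, among them Cd36, Vnn1, Acot1, Mogat1, Cyp4a12a, Ehhadh and Pex11a, where independent lists would share 5.17. A further 79 were lower in both, among them Cela1, Inhba, Apoa4, Pklr and C1s1, where independent lists would share 3.99. Cyp2b10 was the 1 gene called higher with permethrin and lower with clofibrate, and 0 genes were called in the opposite sense. Of the genes called with permethrin, 78.9% were called with clofibrate in the same direction. The log2 changes had a Pearson correlation of 0.67 and a Spearman correlation of 0.59 across 12476 genes, which are not independent replicates. Simulations without any effect gave 0.50 for the Pearson correlation, since both comparisons use the same 3 controls, and 0 genes called in both in each of 20 runs. Without effects the adjustment leaves almost no calls. That 0 therefore does not show how many shared calls the shared controls add when effects exist. The covariance was 0.122 against 0.0431 in the simulations, a difference of 0.0793. The share of genes with the same sign was 71.7% against 66.7%. The counts expected for independent lists take no account of the shared controls. The simulations share them but draw noise for each gene independently, so part of the excess may still come from the shared controls. A split of the controls between the comparisons was not run.

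**Figure D3:**
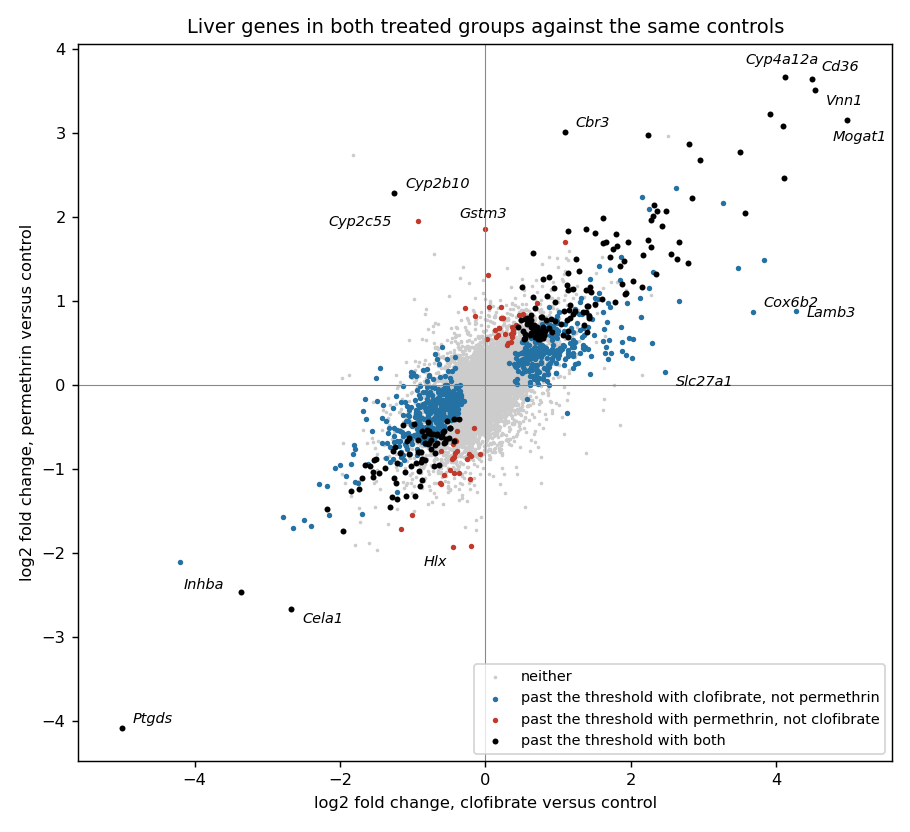
Log2 fold change of each of 12476 genes with clofibrate (horizontal) and permethrin (vertical) against the same 3 controls; colours mark genes past the limma threshold in either or both comparisons. Genes called in both comparisons changed in the same direction except Cyp2b10, and some genes called in 1 of them lie far from the diagonal. Cyp2b10, at -1.26 and 2.28, is the one called in opposite directions.

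The direct comparison of permethrin with clofibrate tests where the diets differed at the same dietary concentration and time. Cyp2b10 was 11.6-fold higher with permethrin, at 3985 ± 309 against 342 ± 53.4 (SD, n = 3). Cyp2c55 was 7.34-fold higher, at 217 ± 88.6 against 25.3 ± 4.14, and Gstm3 3.64-fold higher, at 6249 ± 264 against 1727 ± 255 (SD, n = 3). Cox6b2, an isoform of a cytochrome c oxidase subunit, was 7.01-fold lower with permethrin, at 24.6 ± 6.45 against 208 ± 101.3 (SD, n = 3). Of 12476 genes, 92 passed the limma threshold, 59 higher and 33 lower with permethrin.

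CAR and NRF2 targets, lists that both hold Gstm3, were higher with permethrin than with clofibrate. CAR targets had 10 of 30 genes higher and 0 lower (17 and 0 adjusted over the list alone, median 0.37), and the camera call held with an estimated correlation (adjusted p = 1.4e-13, and 0.0249 with the estimate). Cbr3 was 3.78-fold, Cyp2c54 2.79-fold and Gsta2 2.41-fold higher. NRF2 targets had 7 of 29 higher and 0 lower (14 and 0 adjusted over the list alone, median 0.43), and this call held as well (adjusted p = 1.04e-14, and 0.00363 with the estimate). ER stress genes had 7 of 28 higher and 0 lower (18 and 1 adjusted over the list alone, median 0.59, camera adjusted p = 3.47e-11, adjusted p = 0.129 with an estimated correlation). Under scaling to the hybridization controls 0 of them passed limma, with a median of 0.36, which is 0.58 relative to the median gene, and the camera call at the preset correlation was lost in 0 of 20 settings. Pdia6, a disulfide isomerase of the ER, had a log2 difference of 1.13 ± 0.17 (limma adjusted p = 0.0139), which was 1.04 and no longer past the threshold without clofibrate replicate 3 (adjusted p = 0.0812, where the alternatives ranged from 0.00352 to 0.125). Phase II conjugation had 3 of 25 higher and 0 lower (5 and 0 adjusted over the list alone, median 0.24, camera adjusted p = 0.000135, adjusted p = 0.252 with an estimated correlation).

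Further lists were called higher with permethrin than with clofibrate. The periportal list had a median difference of 0.27 (camera adjusted p = 8.21e-05, adjusted p = 0.23 with an estimated correlation), with 0 of 17 genes past limma, 6 with an unadjusted p under 0.05 and 6 adjusted over the list alone. Complement and coagulation had 1 of 34 genes higher (5 adjusted over the list alone, median 0.18, camera adjusted p = 4.23e-05, adjusted p = 0.226 with an estimated correlation), with a median of -0.05 under scaling to the hybridization controls, 0.17 relative to the median gene. Bile acid genes had 1 of 27 higher (5 adjusted over the list alone, median 0.18, camera adjusted p = 0.000623, adjusted p = 0.157 with an estimated correlation), with a median of -0.05 under that scaling, 0.18 relative to the median gene. PXR targets had 1 of 11 higher (2 adjusted over the list alone, median 0.24, camera adjusted p = 0.00683, adjusted p = 0.252 with an estimated correlation), a call that ended without permethrin replicate 1 and without clofibrate replicate 1. The urea cycle and amino acid list had a median of 0.12 (camera adjusted p = 0.0154, adjusted p = 0.72 with an estimated correlation), -0.11 under the scaling above and 0.11 relative to the median gene, with 0 of 42 genes past limma and 13 with an unadjusted p under 0.05. That call ended without the same arrays as the PXR call, under that scaling and under quantile and cyclic loess normalization.

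Some lipid lists were lower with permethrin than with clofibrate. Mitochondrial fatty acid oxidation had 3 of 23 genes lower and 0 higher (12 and 0 adjusted over the list alone, median -0.29, camera adjusted p = 1.06e-08, adjusted p = 0.252 with an estimated correlation). Cholesterol synthesis had 2 of 21 lower and 0 higher (9 and 0 adjusted over the list alone, median -0.52, camera adjusted p = 9.68e-10, adjusted p = 0.252 with an estimated correlation). Peroxisomal fatty acid oxidation had 3 of 29 lower and 0 higher (6 and 0 adjusted over the list alone, median -0.17, camera adjusted p = 0.000668, adjusted p = 0.55 with an estimated correlation). Fatty acid uptake had 2 of 19 lower and 0 higher (7 and 2 adjusted over the list alone, median -0.29, camera adjusted p = 0.0034, adjusted p = 0.602 with an estimated correlation). The last 2 calls ended without clofibrate replicate 2. Acot1 differed by a log2 value of -1.02 ± 0.14 and Slc27a1 by -2.32 ± 0.30 (limma adjusted p = 0.00869 and 0.00768), and neither was past the threshold without clofibrate replicate 3, at -1.0 and -2.22. Other PPAR alpha targets had 1 of 22 lower and 1 higher (5 and 1 adjusted over the list alone, median -0.26, camera adjusted p = 0.00301, adjusted p = 0.336 with an estimated correlation). The lists of lipid droplet, fatty acid and triglyceride synthesis, peroxisome assembly, omega oxidation and lipoprotein genes were not called (camera adjusted p = 0.229, 0.25, 0.264, 0.696 and 0.273), but were in 3, 4, 2, 0 and 1 of 20 settings. They had 0 genes past limma each, and 4, 9, 4, 4 and 8 at an unadjusted p under 0.05.

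camera called 16 of the 41 lists, and the CAR and NRF2 lists were those that held with an estimated correlation. All 92 called genes had groups that did not overlap, as had 18.1% of the 12476 genes, where chance gives 10%. A difference of at least 2-fold was seen for 38 called genes, 18 higher and 20 lower. The higher to lower split was 51 to 46 with cyclic loess normalization and 9 to 52 under scaling to the hybridization controls. Without permethrin replicates 1 and 2 the counts were 46 and 57, and without clofibrate replicates 2 and 3 they were 50 and 17.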

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

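Of the tests in this part, the one on the other Cyp2b10 probe sets was chosen only after the result was seen, as were the cyclic loess and hybridization control scalings after the data were seen. Cyp2b10 stood out because the direct test found that its response differed between the 2 treated groups: its log2 change was 2.28 ± 0.18 with permethrin and -1.26 ± 0.18 with clofibrate, a difference of 3.54 ± 0.18 (SE; limma adjusted p = 1.20e-05; n = 3 arrays per group). Its 3 permethrin arrays lay above, and its 3 clofibrate arrays below, the 3 control arrays. A difference in array scaling between the groups could turn the clofibrate change, but over 4 other scalings the value nearest to 0 was -0.90, so scaling does not account for the opposite signs. A probe set that misreads a related transcript would stand alone, and the 2 other Cyp2b10 probe sets showed the same opposite changes, at 2.47 and -1.32 and at 2.85 and -1.44. Whether all 3 probe sets also read relatives of Cyp2b10 was not tested, and an effect of the diets themselves stays open as an untested hypothesis.

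The counts of genes were set against other splits of the same 6 arrays into 3 and 3. With permethrin against control, 1 of the 10 splits, the real one, gave 265 genes, and the highest of the others gave 0 with limma (at most 804 genes at an unadjusted p under 0.05). With clofibrate against control, 1 of the 10 splits, the real one, gave 877 genes, and the highest of the others gave 1. With permethrin against clofibrate, 1 of the 10 splits, the real one, gave 92 genes, and the highest of the others gave 1. With 10 splits, a share under 0.05 is out of reach.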

How the results depend on the processing

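Cyclic loess normalization and scaling to the hybridization controls were chosen only after the data were seen. For permethrin against control, clofibrate against control and permethrin against clofibrate, the 265, 877 and 92 genes became 79, 398 and 10 without the intensity trend in the variance model, and 102, 292 and 38 at a threshold of at least 2-fold, which removes smaller changes by construction. Array weights gave 1496 for clofibrate against control and 226 for permethrin against clofibrate. Scaling to the hybridization controls gave 157 for permethrin against control and 61 for permethrin against clofibrate. For the latter, a filter at the 75th percentile gave 139 with fewer probe sets tested, and only the 6 arrays compared gave 47 with fewer arrays in the model. Leaving out 1 array gave 108 to 317, 430 to 889 and 17 to 119 genes, with fewer arrays in the model. A replicate block gave 204, 727 and 62. Except for the 2-fold threshold, the cause of these changes was not tested. The other settings for these counts stayed within 1.5 times the values given first. That holds for the count alone with clofibrate against control under scaling to the hybridization controls. There 1230 genes were called, 1153 higher and 77 lower, and 480 of them were among the 877.

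The 20, 25 and 16 lists called by camera became 2, 1 and 2 with an estimated correlation. The mixed fry test called 31 lists for permethrin against control and 27 for permethrin against clofibrate, and fry in 1 direction called 4 for the latter; fry asks another question than camera. Leaving out 1 array gave 18 to 24, 21 to 28 and 15 to 19 lists. The correlation of the 2 responses, 0.67, lay between 0.62 and 0.74 over the other settings and between 0.61 and 0.71 without 1 array, with a jackknife standard error of 0.0985 over arrays.

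Of the named calls, 29 of 57, 66 of 117 and 5 of 27 held in every setting run. The values of called genes kept direction and side of the threshold in 1293 of 1473, 2680 of 3033 and 572 of 698 gene and setting pairs, and fell short of the threshold in 180, 348 and 126. Fabp1 with clofibrate changed sign from -0.35 to 0.0218 with quantile normalization and to 0.00765 with hybridization scaling, B2m from -0.29 to 0.000242 and 0.0680, and Atp5h from -0.34 to 0.0239 with hybridization scaling; the cause was not tested. Genes short of the threshold passed it in 61, 73 and 74 pairs. Detection calls were not used, so how far signals lie above background is unknown, and genes near the filter of 15.6 are measured least well.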

Other observations

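The tests of pancreatic tissue and of the share of hepatocytes were chosen only after the results were seen. Genes with higher expression in male liver fell with clofibrate in 6 of 21 cases and rose in 2 (8 and 2 adjusted over the list alone, median -0.53, camera adjusted p = 0.00601, adjusted p = 0.173 with an estimated correlation). The largest fall was that of Hsd3b5, a steroid dehydrogenase, at 544 ± 565 in controls and 28.4 ± 24.7 with clofibrate (SD, n = 3), a call that ended without control replicate 2 or 3 or clofibrate replicate 3. The related gene Hsd3b2, which is in no list, fell 5.27-fold. Cyp4a12a, a male-biased gene, rose with both diets. With permethrin the male-biased list had 2 genes higher and 1 lower of 21 (5 and 4 adjusted over the list alone, camera adjusted p = 0.736). Against clofibrate it was higher with permethrin, by 3 genes with 0 lower (3 and 0 adjusted over the list alone, median 0.38, camera adjusted p = 6.94e-05, adjusted p = 0.157 with an estimated correlation). Female-biased genes had 2 of 15 higher and 0 lower in each treated group (2 and 0 adjusted over the list alone, camera adjusted p = 0.736 and 0.188). Those were Cd36 and Acot3. In the clock list, 0 of 18 genes passed limma with permethrin, 3 had an unadjusted p under 0.05, and 2 were lower with clofibrate (camera adjusted p = 0.253 and 0.655). One of them, Cry1, fell 2.35-fold. With clofibrate 7 of the 18 clock genes had an unadjusted p under 0.05. Adjusted over the list alone, 2 were higher and 4 lower, so the list changed in both directions (mixed fry adjusted p = 0.00395).

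Genes of cell division gave few calls. In the cell cycle list, 0 of 37 passed limma with permethrin (3 at an unadjusted p under 0.05), and 1 was lower with clofibrate (camera adjusted p = 0.736 and 0.371). The list was called in 2 of 20 settings in each group, and with permethrin it was called lower without control replicate 1, where the test with all arrays pointed up. Mki67 had log2 changes of 0.50 ± 0.58 with permethrin and 0.08 ± 0.58 with clofibrate, which were -0.30 and -0.72 without control replicate 1, and Ccnd1 of 0.03 ± 0.32 and 0.50 ± 0.32. For p53 targets 0 of 19 genes passed limma in either treated group, with 1 and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.354 and 0.102), with a call in 1 of 20 settings with clofibrate. Immediate early genes had 1 of 16 lower with permethrin and 0 past limma with clofibrate, where 3 had an unadjusted p under 0.05 (camera adjusted p = 0.736 and 0.147), with a call in 1 of 20 settings with clofibrate. Against clofibrate they were lower with permethrin in camera (median -0.27, adjusted p = 0.0181, adjusted p = 0.505 with an estimated correlation), a call that ended without permethrin replicate 1, clofibrate replicate 1 or clofibrate replicate 3 and under scaling to the hybridization controls. ER stress genes had 0 of 28 past limma with permethrin, with 9 at an unadjusted p under 0.05 (median 0.13, camera adjusted p = 0.0854), and were called in 2 of 20 settings. PXR targets had 1 of 11 higher with permethrin, and 1 higher and 3 lower with clofibrate (camera adjusted p = 0.918 and 0.055), and were called with clofibrate in 4 of 20 settings. Cyp3a11, a PXR marker, had a signal of 11305 ± 379 in controls and 10061 ± 477 with permethrin (SD, n = 3; limma adjusted p = 0.481). The highest signal of an array was 14386.9 to 14898.7 in controls and 12791.6 to 13408.5 with permethrin. Cyp3a11 lay near it, so a rise could be hard to read. Cyp3a13 in the PXR list had signals of 419 to 676 in controls and 1215 to 2547 with permethrin. Of the 11 PXR members, 5 had positive and 6 negative log2 changes with permethrin. AHR targets had 0 of 7 past limma with permethrin, with 3 at an unadjusted p under 0.05, and 1 lower with clofibrate, Cyp1a2, by 1.89-fold (camera adjusted p = 0.885 and 0.535).

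Some further lists were not called, in both treated groups unless only 1 is named, with camera adjusted p for permethrin and then clofibrate. Ribosomal proteins had 0 of 23 genes past limma in either, with 1 and 6 at an unadjusted p under 0.05 (0.416 and 0.0721). Oxidative phosphorylation had 0 of 41 past limma with permethrin, 4 at an unadjusted p under 0.05, and 1 higher and 1 lower with clofibrate (0.684 and 0.86). Housekeeping genes had Hprt higher in both, by 1.65-fold and 2.06-fold, and 2 of 13 lower with clofibrate (0.885 and 0.434). The Hprt call with permethrin ended without any 1 control and without permethrin replicate 3. Macrophage markers had 0 of 16 past limma in either, with 0 at an unadjusted p under 0.05 (0.0792 and 0.42). Cholangiocyte markers had 0 of 7 past limma in either, with 0 at an unadjusted p under 0.05 (0.736 and 0.655). T, B and NK cell markers had 0 of 9 past limma in either, with 0 and 1 at an unadjusted p under 0.05 (0.416 and 0.535). Neutrophil markers had 1 of 8 higher in both (0.736 and 0.42). Phase II conjugation and bile acid genes with permethrin had 1 of 25 and 2 of 27 higher (0.205 and 0.918 in that group), with 9 and 12 at an unadjusted p under 0.05. Adjusted over the list alone, phase II had 2 higher and 1 lower, and the bile acid list 4 higher and 5 lower. Both changed in the mixed fry test (adjusted p = 0.000219 and 4.82e-07). The pancreas list with clofibrate had Cela1 lower (0.147). Stellate and endothelial markers with permethrin had 0 of 18 past limma each, with 3 and 4 at an unadjusted p under 0.05 (0.239 and 0.112). Of 20 settings, 1 called ribosomal, 3 macrophage, 1 stellate and 1 endothelial genes with permethrin, and 4 called oxidative phosphorylation with clofibrate. The pancreas list with clofibrate was called in 1 of 19 settings. Ketone body synthesis, erythroid and adipose lists had 4 tested genes each and were not tested as lists; with clofibrate 1 ketone gene rose, and in the adipose list 1 rose and 1 fell, while the erythroid list had 0 past limma and 0 at an unadjusted p under 0.05.

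Median, mean and test differed in sign for some lists. With permethrin these were bile acid (median -0.08, mean 0.01), female-biased (-0.24 and -0.01, test up), male-biased (-0.06 and 0.04), cell cycle (-0.01 and -0.01, test up), housekeeping (-0.06 and 0.06), neutrophil (-0.21 and 0.05) and AHR genes (0.03 and -0.02). With clofibrate it was the T, B and NK cell list (-0.08 and 0.17). For permethrin against clofibrate these were the acute phase list (-0.18 and -0.28, test up), heat shock (0.06 and -0.12), lipoprotein (0.11 and -0.01), cholangiocyte (-0.05 and -0.06, test up) and T, B and NK cell lists.

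Cela1 was lower in both treated groups, by 2.66 ± 0.20 and 2.67 ± 0.20 on the log2 scale (SE, n = 3 per group). Pancreatic tissue in the control livers could give this, but it would bring all its abundant transcripts. The 13 other pancreas genes with a probe set of their own had control mean signals from 1.98 to 38.2, against 1295 ± 189 for Cela1 (SD, n = 3). Probe sets differ in how signal follows abundance, which limits this comparison for any single gene, though all 13 lay far below. The brightest, Cela3b, Prss2 and Cela2a, moved by -0.54, -1.19 and -0.71 with permethrin and by 0.06, -0.16 and -1.40 with clofibrate. The camera call of the list with permethrin (adjusted p = 0.00793, adjusted p = 0.122 with an estimated correlation) includes Cela1 itself. Pancreatic tissue as the source of the Cela1 change is argued against by these levels, a trace of it is not excluded, and a change of Cela1 in the liver itself stays open as an untested hypothesis.

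Complement and coagulation genes had a median log2 change of -0.37 with permethrin and -0.49 with clofibrate. A bias that depends on signal could lower abundant genes together, but the list's median lay at percentile 0 of 10000 lists matched in signal in both groups, whose medians were -0.07 (95% between -0.16 and 0.03) and -0.15 (95% between -0.29 and -0.01). A lower share of hepatocytes could also lower them, and would raise markers of other cell types if those types kept their numbers. Endothelial markers had medians of -0.11 with permethrin and -0.15 with clofibrate, and stellate markers -0.14 and -0.40. Macrophage markers had 0.14 and 0.11. With permethrin camera called none of these lists (adjusted p = 0.112, 0.239 and 0.0792). With clofibrate the macrophage list was not called (camera adjusted p = 0.42). The endothelial and stellate calls were lost in 12 and 9 of 20 settings. These cell types need not change alike, and the lists were not tested against each other. A lower share of hepatocytes is therefore not excluded. Under hybridization scaling the endothelial medians were 0.02 and 0.20, but they stayed below the median gene, by -0.06 and -0.10. Macrophage markers lay above it, by 0.19 and 0.14. An effect of the diets on these genes stays open as an untested hypothesis, as does the shift of all genes under that scaling.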
